A study of Mus musculus with 3 samples.

How the data were processed

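DNase-seq was run on 3 libraries of primary monocytes from female B6CASTF1/J mice of 2 months. The labels number them as biological replicates 1, 2 and 4, with 1 technical replicate each and 1 shared donor identifier, and all formed 1 group. The deposited description of each library names the mm10 assembly and says that its files were derived from the filtered alignment of that library, so peaks were called per library and not on pooled reads. The aligner, the peak caller and the footprint method are not given in the sources used here.

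Each library had 2 deposited lists of peaks, each peak with its position and 1 height, a signal of cleavage density that the authors computed and gave in whole multiples of 1 step per library. The scale of that height, and whether it was set by depth, is not stated. The height belongs to the peak as the authors called it, and was used to rank and filter peaks within a library and to describe their size. In crowded windows, ratios of heights between libraries were divided by the ratio typical of shared regions; elsewhere they are as deposited. The columns for score, p-value and q-value of the deposited peak lists held 1 constant and were not used. A further deposited file gave the false discovery rate (FDR) of cleavage along the genome as the authors computed it, listed where it was under 0.05. Every peak of the longer list overlapped such an interval, with a best FDR of up to 0.0499, while the best FDR of peaks in the shorter list stayed under 0.001 (largest 0.000998). By the rule fixed in advance the longer list was used throughout, and the shorter, stricter one, with 36568, 28631 and 34672 peaks, was an alternative. The deposited footprints carried a single value of the p-value kind for all footprints, which ranks nothing and was not used.

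Reference sequence and genes came from the GRCm38.p6 assembly, whose chromosome lengths contained every peak, and the GENCODE M21 basic annotation (release number 21). Peaks on chromosomes 1 to 19, X and Y were kept. The annotation gave 21911 protein-coding genes with 41438 TSSs. A promoter peak is a peak that overlaps the window of 1000 bp on either side of any protein-coding TSS of the gene. A distal peak lies outside all such windows, and was counted for a gene when it fell within 50000 bp of its most upstream protein-coding TSS. For 3482 genes that position differs from the 5' end of the gene record, and the use of the coding TSS was settled after the data were seen. Genome classes were assigned to the midpoint of a peak in the order promoter, exon, intron and intergenic. Libraries were compared by overlaps of at least 1 bp and by merging all peaks into regions.

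A total of 27 gene lists were fixed before the data were examined: the monocyte list, 14 lists of other lineages (neutrophil granule, dendritic, B, T, natural killer, erythroid, megakaryocyte, mast cell and basophil, stem and progenitor, tissue macrophage, neuronal, hepatocyte, muscle, epithelial), housekeeping genes, myeloid transcription factors, classical and nonclassical monocyte subsets, and 8 functional groups (pattern recognition, Fc and complement receptors, chemokine receptors, major histocompatibility complex class II, NADPH oxidase, interferon response, cytokines, lysosome). Of their genes 2, Clec7a and Mx2, did not match a protein-coding symbol. The monocyte list was compared with each lineage list by Fisher's exact test of promoter peaks in all 3 libraries and by a permutation test of the mean number of distal peaks with 100000 resamples, both two-sided, with genes in both lists left out. Calls were made at an adjusted p of 0.05 (Benjamini-Hochberg over 14 lists). Each list was also ranked among 10000 random lists of its size, with ties counted as 0.5, and among random lists matched on the number of TSSs in the window. Random lists were drawn gene by gene and do not reproduce neighbouring members that share distal peaks. Distal ranks of lists with clustered genes can therefore look more extreme than they are. Genes were named by a rule fixed with the lists: for each list up to 4 members with the largest mean number of distal peaks and up to 4, in alphabetical order, that lacked a promoter peak in at least 1 library, any myeloid transcription factor, and the 25 genes with the most distal peaks in the genome, skipping genes within 50 kb of one already taken.

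Footprints inside peaks were extended by 5 bp on each side and searched on both strands for 32 consensus patterns, set beside windows of the same width placed at random in the same peaks away from footprints. Control windows could be placed for 123919, 94392 and 102969 footprints. Log2 ratios used a pseudocount of 0.5, and a motif was called when Fisher's exact test passed in the same direction in all 3 libraries. Y regions were compared with the other chromosomes by blastn 2.17.0, keeping the longest single alignment of each region. Promoter CpG content was the observed over expected CpG ratio within 500 bp of the most upstream protein-coding TSS, matched in 20 bins. Promoter peaks counted at any protein-coding TSS, so the CpG content of a gene's other promoters was not matched. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

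The scripts were tested on simulated data. In 100 simulations on 21911 genes the promoter test called 95.3% of lists drawn with 5% against 70% of promoters and 2.29% of lists drawn alike. The distal test called 100% of lists with means of 1.2 against 4.8 and 1.71% of lists with equal means. Both simulations drew each gene independently, with Poisson counts for distal peaks. They therefore do not cover list members that share peaks, counts with a wider spread, or smaller contrasts. All 8 planted motifs and 0 of 24 others were called, and overlaps equalled a direct count for all 400 intervals tested. The simulated sequence was drawn with the same base composition throughout. The motif check therefore does not cover the higher G and C content of the real footprints. The depth of a library is not stated, so no counting error could be put on a peak, and errors are the SD over 3 libraries. Alternatives were the shorter list, the taller 50% of peaks, the same number of peaks in each library, other windows and overlaps, other extensions, distal footprints, and leaving out each library. A minimum height of 0.4, the 5' end of the gene record, and single libraries for the monocyte subsets were added after the data were seen.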

Results

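Chromatin accessibility was measured by DNase-seq in mouse monocytes, circulating phagocytes of the innate immune system that give rise to macrophages. The primary cells came from female adult mice of 2 months of the B6CASTF1/J strain, a first-generation cross of the inbred strains C57BL/6J and CAST/EiJ. In this assay the nuclease DNase I cleaves chromatin where it is open, so that peaks of cleavage mark accessible promoters and regulatory elements. Short stretches with less cleavage inside them, called footprints, can mark places where a protein shielded the DNA. The series held 1 group of 3 libraries, labelled biological replicates 1, 2 and 4 and tied to a single donor identifier. Nothing in the labels says that the libraries came from separate animals, so errors below measure the spread between these libraries, which may be technical. With a single cell type, the comparisons the design allows are those between libraries, between gene lists, between sequence classes and between chromosomes. Every peak height was a whole multiple, to within 0.05 of a step, of 1 step per library. The steps were 0.00825, 0.00887 and 0.0124 in replicates 1, 2 and 4. If heights were divided by the number of cleavages, which is not stated, replicate 4 was the shallowest library and replicate 2 was 1.40 times as deep.

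The promoters of several myeloid regulators stood among the tallest accessible sites of every library. The promoter peak of Klf2, a Krüppel-like factor that restrains monocyte activation, ranked at percentile 99.4, 99.6 and 99.3 of all peak heights in replicates 1, 2 and 4. That of Cebpa, which directs myeloid commitment, ranked at 99.1, 99.2 and 99.2, and that of Nr4a1, a nuclear receptor needed for patrolling monocytes, at 98.1, 98.4 and 98.7. The promoter of the beta-actin gene Actb, a housekeeping gene, ranked at 99.8 in each library. Spi1, the gene of the myeloid master regulator PU.1, ranked lower, at 87.9, 85.7 and 84.8. Promoter peaks were tall in general. Over 10708 autosomal genes with one in all libraries the median height was 3.97, 3.30 and 5.05, against 3.75, 3.30 and 4.23 for Spi1. Among the taller 50% of peaks the regulator genes Gfi1 and Tfec had no promoter peak in any library, Mef2c had one in 1 and Batf in 2. Peaks numbered 54046, 42657 and 48980 in replicates 1, 2 and 4 (48561 ± 5706, SD, n = 3), had a median width of 200 bp in each library, and covered 11.5, 8.78 and 9.86 Mb. Merging them gave 63420 regions, of which 34441 (54.3%) held a peak of all 3 libraries, 9389 (14.8%) of 2 and 19590 (30.9%) of 1. Regions seen in a single library were low: their median height was 0.462 ± 0.0454, against 1.43 ± 0.240 for regions seen in all 3 (SD, n = 3). Replicate 1, with the most peaks, held 51.3% of the regions seen in 1 library. Between pairs of libraries, 69.5% to 88.5% of the peaks of one overlapped a peak of the other by 1 bp or more. Across the 34441 shared regions, which are not independent replicates, heights had a Spearman correlation of 0.953 to 0.959 between pairs. The shared percentage rose to 70.2% when the taller 50% of each library's peaks were used.

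Accessible sites were concentrated at gene starts. Sequence within 1 kb of a protein-coding transcription start site (TSS) makes up 2.08% of the assembled autosomes and X chromosome and held 35.2% of peaks (33.4%, 37.9% and 34.3% in replicates 1, 2 and 4), a 16.9-fold ± 1.15 excess (SD, n = 3). Exons outside that window held 3.47% ± 0.0983 of peaks, 1.43-fold ± 0.0404 their share of the genome. Introns held 28.9% ± 1.57 and intergenic sequence 32.4% ± 0.759, which were 0.789 ± 0.0428 and 0.551 ± 0.0129 times their shares. Peaks near a TSS were also taller, with a median height of 1.98 ± 0.366 against 0.849 ± 0.0800 for distal peaks (SD, n = 3), a difference in the same direction in each library. Of 21911 protein-coding genes, 11011 (50.3%) had a promoter peak in all 3 libraries and 9709 had none in any. The classes differed from their shares of the genome by more than the spread between libraries. No test was run on them.

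At the loci of 3 central monocyte genes, accessible regions lay in the promoter and spread over upstream and intronic sequence (mm10 coordinates). Spi1 (ENSMUSG00000002111.8, chromosome 2, 91082390 to 91115756, plus strand) had a promoter region at 91096581 to 91096840 with a height of 3.76 ± 0.467 and a taller one at 91082901 to 91083260, upstream of its first protein-coding TSS and inside the non-coding 5' part of the gene record, with a height of 5.30 ± 0.847 (SD, n = 3). Csf1r (ENSMUSG00000024621.16, chromosome 18, 61100598 to 61132149, plus strand) encodes the receptor for the growth factor that sustains monocytes and macrophages. Its tallest region was not the promoter, at 61105501 to 61106117 with a height of 1.17 ± 0.170, but an intronic region at 61108501 to 61108800, 3.08 kb downstream of the TSS, with a height of 4.14 ± 0.925 (SD, n = 3). Cx3cr1 (ENSMUSG00000052336.7, chromosome 9, 119901616 to 120069879, minus strand) encodes the fractalkine receptor of patrolling monocytes. In the part of its introns within 50 kb of the TSS, the tallest region, at 120054921 to 120055260 and 14.8 kb downstream of the TSS, had a height of 2.85 ± 0.903. The rest of this long gene was not examined. Around Cebpb (ENSMUSG00000056501.3, chromosome 2, 167688915 to 167690418, plus strand), which encodes a transcription factor of monocyte differentiation, the tallest region lay 3.57 kb upstream in an intron of Tmem189, at 167685241 to 167685440, with a height of 7.30 ± 1.75, above the 6.34 ± 1.78 of the region over the Cebpb TSS (SD, n = 3). That upstream region held the CTCF consensus match CCACGAGATGGC at 167685324 to 167685335 under footprints of all 3 libraries. By contrast, the window of 50 kb on either side of the TSS of Alb (ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602, plus strand), the gene of the hepatocyte product albumin, held 1 region, in an intron of Afp at 90500841 to 90501020, with a height of 0.749 ± 0.112 (SD, n = 3).

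**Figure D1:**
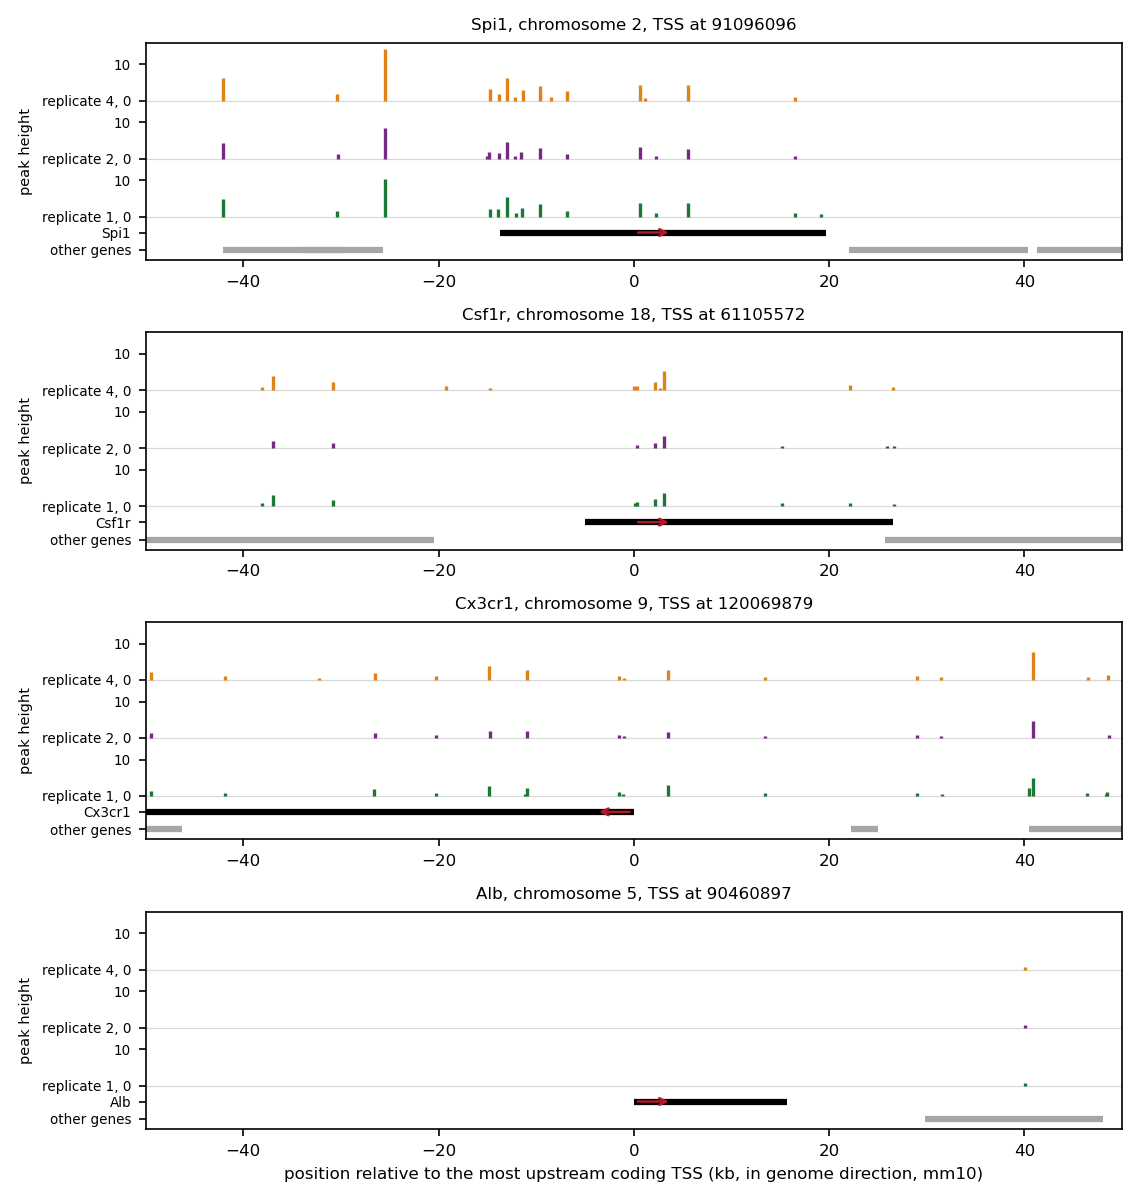
Heights of the authors' DNase-seq peaks (vertical lines, in the deposited height unit, 1 band per library) within 50 kb of the most upstream protein-coding TSS of Spi1, Csf1r, Cx3cr1 and Alb; black bars are the named gene, grey bars other protein-coding genes, and red arrows start at the TSS and point in the direction of transcription. The first 3 loci held several regions each, whereas the Alb window held 1, with a height of 0.749 ± 0.112 (SD, n = 3).

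Promoters of monocyte genes were accessible more often than those of genes of lymphocytes, erythroid cells, mast cells and basophils, hepatocytes and epithelium. Of 15 monocyte genes, 9 (60%) had a promoter peak in all 3 libraries, among them Csf1r, Cx3cr1 and Itgam, which encodes the integrin chain CD11b. Of the members without one in every library, the chemokine receptor gene Ccr2 and the secreted chitinase-like protein gene Chil3 had none, while the coagulation factor gene F13a1 and the Fc receptor gene Fcgr1 had one in 1 library each. None of 14 hepatocyte genes, Alb, Ahsg, Apoa1 and Apoa2 included, had a promoter peak in any library. The counts were 1 of 15 T cell genes (Cd5), 1 of 14 natural killer cell genes (Cd244a), 1 of 14 erythroid genes (Tal1), 2 of 14 B cell genes (Blnk and Ebf1), 2 of 14 mast cell and basophil genes (Hpgds and Kit), and 2 of 14 epithelial genes.

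Each of those 7 lists differed from the monocyte list by a two-sided Fisher's exact test over genes, with Benjamini-Hochberg adjustment over 14 lists. The adjusted p was 0.0098 for hepatocyte genes, 0.0182 for T cell, natural killer cell and erythroid genes, and 0.0419 for B cell, mast cell and basophil, and epithelial genes. The other 7 lists did not pass. Dendritic cell genes, at 8 of 14, were close to the monocyte list (Fisher's exact test, adjusted p = 1), and 6 of 14 stem and progenitor genes had a promoter peak in all libraries (adjusted p = 0.502). The counts were 4 of 15 neutrophil granule genes (Csf3r, Cebpe, S100a8 and Mmp8) and 4 of 14 muscle genes (Tnni2, Mylpf, Ryr1 and Actn3), each with adjusted p = 0.163 by the exact test. They were 3 of 14 megakaryocyte genes (Itgb3, Nfe2 and Pf4), 3 of 15 tissue macrophage genes (Adgre1, Nr1h3 and Mertk) and 3 of 14 neuronal genes (Syp, Grin1 and Tubb3), each with adjusted p = 0.0846 by the exact test. In every library the monocyte share was above that of all 14 lists. It was not high for genes in general, at percentile 76.5 of random protein-coding lists of 15 genes, but it was high for promoters of equal CpG content, at percentile 99.99 of CpG-matched lists (mean 21.4%). Genes are not independent replicates, and members that make up counts of 5 or fewer were named after their values were seen where the naming rule did not reach them. The calls depended on the peak threshold: the authors' shorter peak list left 2 of the 7 and the taller 50% of peaks left 0 by the same Fisher's exact test, with 4 lists at an unadjusted p under 0.05 and a smallest adjusted p of 0.148. Without replicate 4 the B cell call was lost (Fisher's exact test, adjusted p = 0.0846, 6 calls), and without replicate 2 megakaryocyte and neuronal genes were added (adjusted p = 0.0394 each, 9 calls).

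Distal accessible sites also gathered around monocyte genes. The 15 genes had on average 6.44 ± 1.14 distal peaks within 50 kb of the TSS (SD, n = 3). In replicates 1, 2 and 4 the means were 7.67, 5.40 and 6.27, against 2.68, 2.04 and 2.46 for all protein-coding genes. The list lay at percentile 99.99 of random lists matched on the number of TSSs in the window. Fcgr4, which encodes an activating receptor for immunoglobulin G, had 16 ± 3 distal peaks, Cx3cr1 had 12.3 ± 2.08, and Csf1r had 8.33 ± 1.53 (SD, n = 3). Ccr2, without a promoter peak, had 7 ± 1 distal peaks, and Chil3 had none in any library. Itgam had 19, 5 and 7 in replicates 1, 2 and 4, a mean of 10.3 that fell to 6 without replicate 1, where low peaks crowded its window. Among the other lists the means were lowest for mast cell and basophil genes (1.52 ± 0.360), hepatocyte genes (1.74 ± 0.180) and erythroid genes (2 ± 0.258), all with n = 3.

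The monocyte mean was above that of 10 of 14 lists by a two-sided permutation test over genes (100000 resamples, Benjamini-Hochberg over 14 lists), and above all 14 in each of the 3 libraries. Adjusted p was 0.0007 for mast cell and basophil genes and 0.00252 for hepatocyte, erythroid and tissue macrophage genes, the last with a mean of 2.22 ± 0.329. It was 0.00462 for neuronal genes (2.10 ± 0.338) and, by the same permutation test, 0.00660 for T cell (2.80 ± 0.200), B cell (2.83 ± 0.644), stem and progenitor (2.60 ± 0.546) and muscle genes (2.43 ± 0.689). The permutation test gave 0.0305 for megakaryocyte genes (3.40 ± 0.536). Neutrophil granule genes (4.69 ± 0.468, adjusted p = 0.229) and dendritic cell genes (4.74 ± 0.965, adjusted p = 0.230) did not differ from the monocyte list by this permutation test. Nor did natural killer cell genes (3.62 ± 0.289, adjusted p = 0.0817) or epithelial genes (3.31 ± 0.837, adjusted p = 0.0613) in the permutation test. Single members of these lists reached high counts with no promoter peak: the neutrophil myeloperoxidase gene Mpo had 13.3 ± 1.53 distal peaks, the natural killer cell receptor gene Klrb1c 13 ± 2 and the keratin gene Krt8 14.7 ± 4.16 (SD, n = 3). A window on the genome assigns every peak to all genes in reach, so a peak counted near a gene is not known to act on it. With the taller 50% of peaks 3 calls stood and with a 100 kb window 6, while leaving out replicate 1 lost megakaryocyte genes (permutation test, adjusted p = 0.0787, 9 calls) and leaving out replicate 4 added epithelial genes (adjusted p = 0.0472, 11 calls).

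**Figure D2:**
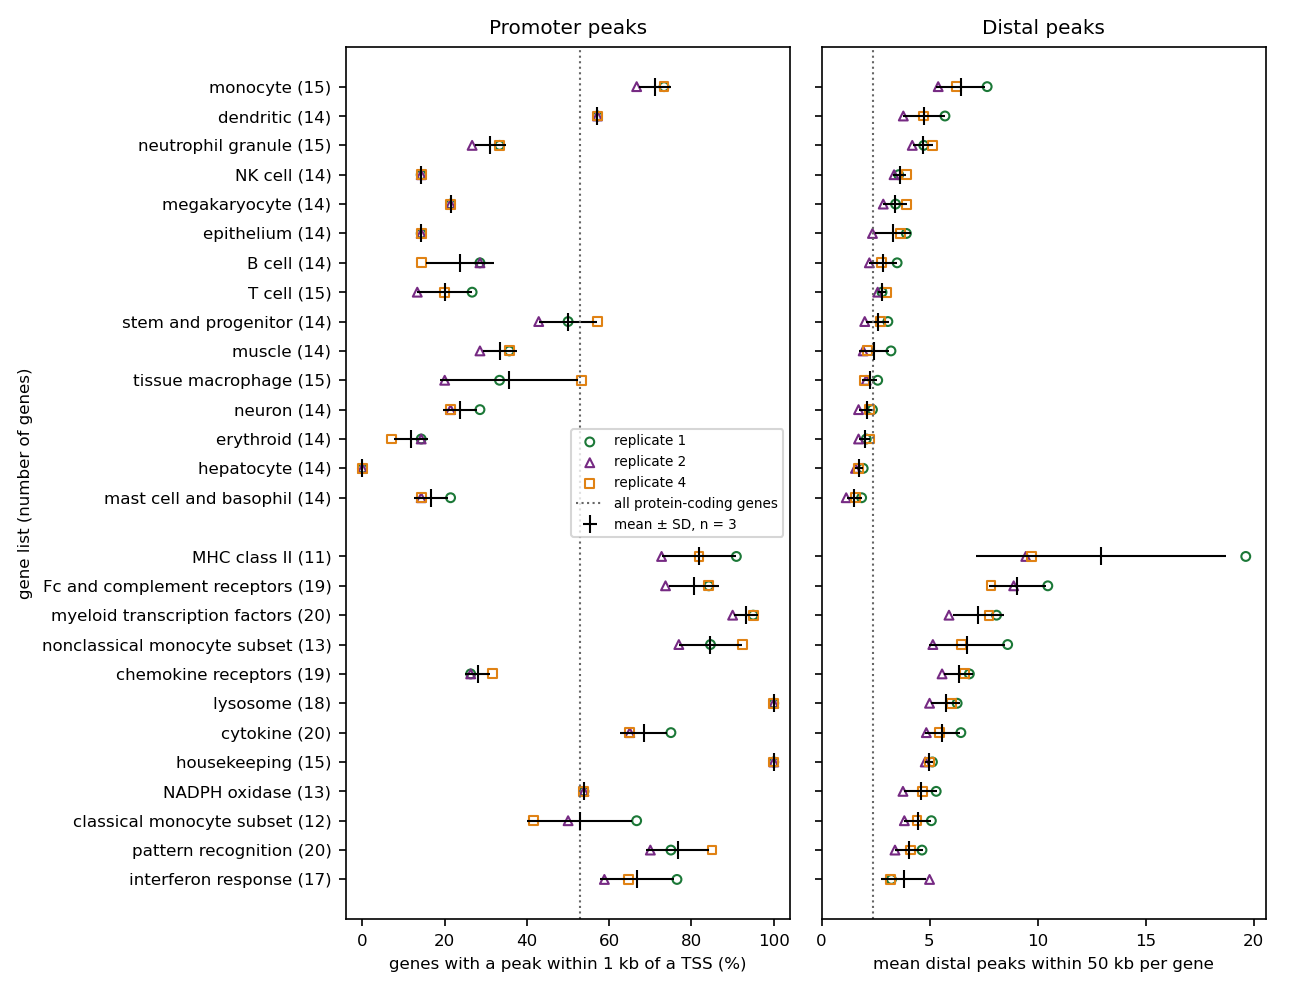
Share of genes with a peak within 1 kb of a TSS (left, percent) and mean number of distal peaks within 50 kb of the TSS per gene (right) for each gene list, with the number of genes in brackets; symbols are the 3 libraries, crosses the mean ± SD (n = 3), and dotted lines the value for all protein-coding genes. Monocyte genes lie at 6.44 ± 1.14 distal peaks, to the right of the 14 other lineage lists, while hepatocyte genes have no promoter peak.

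Genes of myeloid transcription factors carried promoter peaks almost throughout and many distal peaks. Of 20 such genes 18 had a promoter peak in all libraries, the exceptions being Gfi1, with one in 2 libraries, and Tfec, with none. Their mean was 7.25 ± 1.18 distal peaks (SD, n = 3), above each of 10000 random lists matched on TSS number. Cebpb had 19.7 ± 2.52 distal peaks, Klf2 17 in each library, Nr4a1 13.7 ± 3.21 and Spi1 12 in each library (SD, n = 3). Irf8, which encodes an interferon regulatory factor of monocyte and dendritic fate, had 12, 1 and 15 in replicates 1, 2 and 4, so 1 library stood far below the others. Receptors that bind antibody or complement gave 9.07 ± 1.32 distal peaks per gene (SD, n = 3) and promoter peaks in all libraries at 13 of 19 genes. Within that group Fcgr3, an immunoglobulin G receptor gene, had 17 ± 1 distal peaks, Itgb2, the gene of the shared chain of leukocyte integrins, 12.7 ± 2.52, and the anaphylatoxin receptor gene C3ar1, with no promoter peak, 11.3 ± 1.15 (SD, n = 3). Major histocompatibility complex class II genes had the highest list mean, 12.9 ± 5.80, but it was set by replicate 1, at 19.6 against 9.45 and 9.73 in replicates 2 and 4. H2-Ab1, a class II beta chain gene, had 37, 8 and 8 distal peaks in replicates 1, 2 and 4, a mean of 17.7 that fell to 8 without replicate 1. Promoter peaks in all libraries were found at 8 of the 11 class II genes, including Cd74, the invariant chain, with 21, 24 and 9 distal peaks. No test between lists was planned for these groups, which are set against random lists of equal size.

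Among chemokine receptor genes 5 of 19 had a promoter peak in all libraries (Cx3cr1, Ccr1, Ccrl2, Cxcr4 and Cxcr3), at percentile 2.01 of random lists and 77.1 of lists matched on CpG content, and the mean was 6.35 ± 0.677 distal peaks (SD, n = 3), above each of 10000 random lists. Ccr1, a receptor for inflammatory chemokines, had 11.7 ± 1.53 distal peaks, and Ccr8, with no promoter peak, had 11.3 ± 1.53 in a window that overlaps that of Cx3cr1. Random lists do not copy such shared windows, so the distal rank of this list can be overstated. Cytokine and chemokine genes averaged 5.58 ± 0.808 distal peaks, with promoter peaks in all libraries at 12 of 20, and Tnf, the tumour necrosis factor gene, had 11 ± 3.61, while Il1b, the interleukin 1 beta gene, had 9.33 ± 2.08 (SD, n = 3). Csf3, which encodes granulocyte colony-stimulating factor, had 9 ± 1 distal peaks without a promoter peak. All 18 lysosomal genes had a promoter peak in every library and a mean of 5.76 ± 0.672 distal peaks, led by the protease gene Ctsb at 11 ± 4 and Tfeb, a regulator of lysosome formation, at 10.7 ± 2.31 (SD, n = 3). NADPH oxidase genes had promoter peaks in all libraries at 7 of 13 and 4.59 ± 0.774 distal peaks. The promoter of Cybb, which encodes the membrane subunit of the phagocyte oxidase, had no peak in any library. Pattern recognition receptor genes had promoter peaks in all libraries at 13 of 20 and 4.05 ± 0.626 distal peaks, led by Nod2 and Tlr5, sensors of bacterial peptidoglycan and flagellin, at 8.33 ± 0.577 and 8.33 ± 1.53 (SD, n = 3). Interferon response genes had promoter peaks in all libraries at 10 of 17 and 3.80 ± 1.04 distal peaks, at percentile 95.6 of random lists matched on TSS number. That mean was raised by replicate 2, at 5 against 3.24 and 3.18 in replicates 1 and 4, and was 2.98 without peaks under a height of 0.4. The nucleic acid sensor gene Zbp1 had 3, 41 and 3 distal peaks in replicates 1, 2 and 4, so that its mean of 15.7 fell to 3 without replicate 2, and Irf7, the regulator of type I interferon, had 7.67 ± 1.53 (SD, n = 3). The 15 housekeeping genes all had a promoter peak in every library and 4.98 ± 0.168 distal peaks (SD, n = 3).

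Across all protein-coding genes, the 25 with the most distal peaks, spaced at over 50 kb, were of mixed function. Windows of genes less than 100 kb apart still overlap, so some peaks count for more than 1 of the 25. Fosb had 26 ± 1.73 distal peaks and Fos 21 ± 1 (SD, n = 3), both genes of AP-1 subunits that respond within minutes to stimulation. Cebpb, Klf2, Fcgr3 and Cd74 stood among the 25, at 19.7 ± 2.52, 17 in each library, 17 ± 1 and 18 ± 7.94 (SD, n = 3). The signalling gene Gnai2, an inhibitory G protein subunit that acts downstream of chemokine receptors, had 15.7 ± 2.52, and the transglutaminase gene Tgm2 had 16 ± 2.65. Nanos3 had 21.7 ± 3.21 with no promoter peak, in a window that overlaps that of Zswim4 (22.3 ± 3.06, SD, n = 3). The top gene, Gm21887 at the end of the X chromosome (170009659 to 170019281), had 23, 43 and 65 in replicates 1, 2 and 4. H2-Ab1 was among the 25 through replicate 1. Cptp had 20, 26 and 5 in replicates 1, 2 and 4, and its mean of 17 dropped to 4.33 when peaks under a height of 0.4 were left out. No list of genes was tested for being common among the 25.

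Sequence motifs differed in how often they occurred in footprints. Whether the footprint method corrected for the sequence preference of DNase I cleavage is not given, and no correction was made here. Protection by a protein can therefore not be told apart from that preference. The CTCF consensus, bound by the insulator protein CTCF, occurred in 3.48% ± 0.0176 of footprints (SD, n = 3), 47.2-fold more often than in footprint-free windows of the same peaks. The cyclic AMP response element bound by ATF and CREB factors was 18.9-fold more frequent, and the consensus of the CEBP family of monocyte regulators 11.1-fold, with log2 ratios of 4.24 ± 0.68 and 3.48 ± 0.50 (SD, n = 3). The NRF1 consensus, bound by a regulator of mitochondrial and housekeeping genes, was found in 301, 295 and 310 footprints and 2, 2 and 1 control windows of replicates 1, 2 and 4. These counts give ratios of 150.5, 147.5 and 310, with exact 95% counting intervals of 41.3 to 1248, 40.5 to 1224 and 55.2 to 12283. The consensus GRGGAAGTG, called the PU.1 composite below, is an ETS-type pattern that includes sites of PU.1, the factor encoded by Spi1. It was 1.98-fold more frequent in footprints (log2 ratio 0.99 ± 0.08, SD, n = 3), which does not single out PU.1 among ETS factors. The forkhead consensus was depleted to 0.311-fold (log2 ratio -1.68 ± 0.09, SD, n = 3).

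Of 32 consensuses, 10 were over-represented and 3 under-represented in all 3 libraries by a two-sided Fisher's exact test per library, with Benjamini-Hochberg adjustment over all motifs and libraries. Besides NRF1, CTCF, the cyclic AMP response element, CEBP and PU.1, the over-represented ones were SP/KLF (9.13-fold), EGR (5.91-fold), KLF (3.01-fold), the ETS core (2.94-fold) and the E-box of USF and MITF (2.13-fold), and the under-represented ones NFY (0.709-fold) and TEAD (0.664-fold) besides the forkhead consensus. By motif class, 7 of 10 general, 3 of 8 myeloid, 0 of 2 haematopoietic and 0 of 12 other-lineage consensuses were over-represented. The largest adjusted p of the Fisher's exact test in any library was 6.0e-15 for the PU.1 composite, 2.4e-21 for CEBP and 0.0106 for TEAD. Footprints held more G and C than their control windows, 63.7% against 56.4% in replicate 1, so each consensus was also compared with 20 shuffles of its letters, or 8 for SP/KLF, whose letters allow no more. NRF1, CTCF, the cyclic AMP response element, CEBP, SP/KLF and the E-box exceeded every shuffle in every library, whereas EGR, KLF, the ETS core and the PU.1 composite did not, and the forkhead consensus fell below every shuffle. The depleted NFY and TEAD consensuses did not fall below every shuffle. TEAD, at a log2 ratio of -0.59, lay near the median of its shuffles (-0.52), and NFY stood at -0.50 against -0.26. The interferon regulatory factor motif was at a log2 ratio of 0.40 ± 0.06 and did not pass in every library (largest adjusted p = 0.0788, Fisher's exact test, n = 3), although it exceeded every shuffle in every library. With an extension of 10 bp it passed in all 3 (largest adjusted p = 0.00355), as did the NFKB consensus (0.000235, Fisher's exact test). Shuffles were run only with the extension of 5 bp, where NFKB, at a log2 ratio of 0.13, lay below the median of its shuffles (0.45), and 1 of 8 myeloid consensuses, CEBP, was both called and above every shuffle. Footprints numbered 144028, 107955 and 119597 in replicates 1, 2 and 4 (123860 ± 18410, SD, n = 3), of which 88.6% ± 0.531 lay in peaks, and 80.7% ± 1.99 of peaks held one. Merged footprints gave 220635 regions, of which 20.3% were found in all 3 libraries and 61.3% in 1. The PU.1 composite passed with footprints extended by 5 bp, but not without extension (log2 ratio 0.19, largest adjusted p = 0.934, Fisher's exact test). NFY passed neither with an extension of 10 bp (largest adjusted p = 0.454, Fisher's exact test) nor in distal peaks, where TEAD did not pass either (0.128 and 0.483). Over all settings 4 motif calls were lost and 11 gained, the others gained being depletions of GATA, TCF/LEF, POU and P53 consensuses and the interferon regulatory factor motif without replicate 2.

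**Figure D3:**
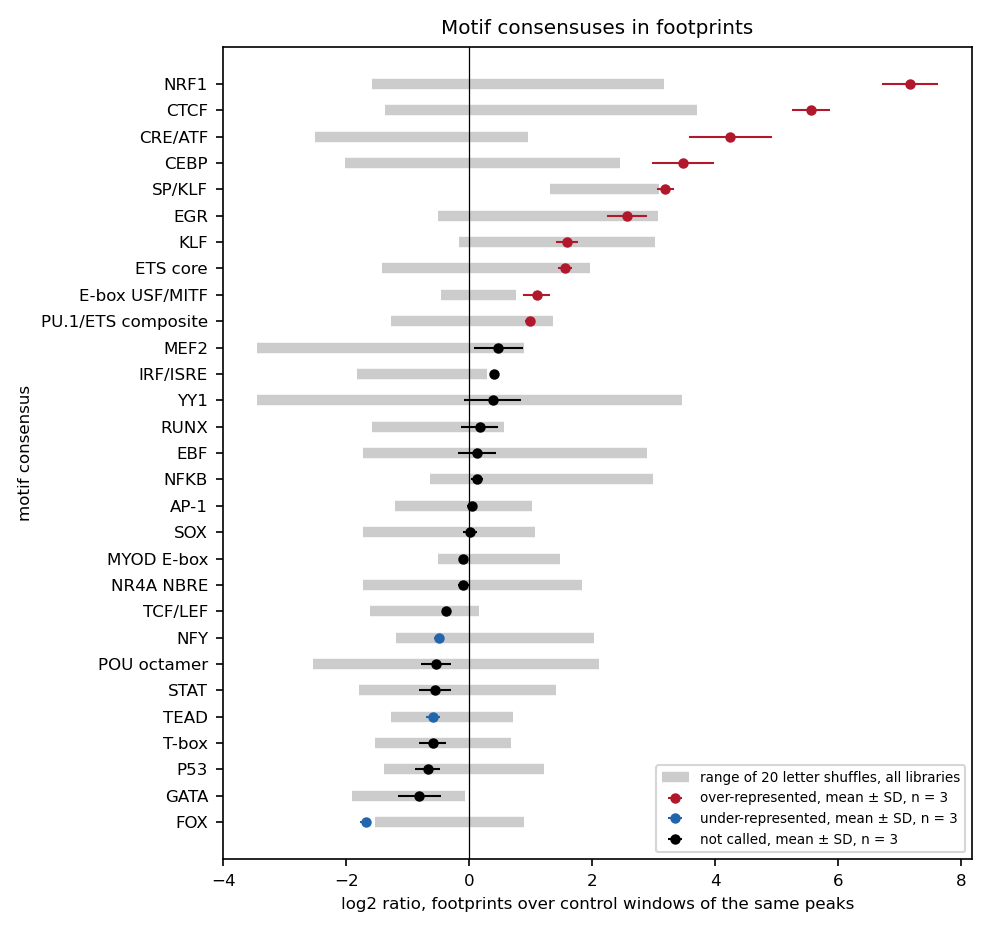
Mean log2 ratio of footprints to footprint-free control windows holding each motif consensus (points, ± SD over 3 libraries), for consensuses with at least 20 footprints in every library; red points were over-represented, blue under-represented and black not called in all libraries, and grey bars span 20 letter shuffles (8 for SP/KLF) over the 3 libraries. NRF1, CTCF, the cyclic AMP response element and CEBP lie right of their bars, at 7.16, 5.56, 4.24 and 3.48, and the forkhead consensus left of its bar at -1.68.

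The X chromosome carried fewer accessible sites than the autosomes. It held 7.21 ± 0.775 peaks per Mb, against 19.8 ± 2.33 on the autosomes, a ratio of 0.365 ± 0.007 (SD, n = 3), while its density of protein-coding genes was 0.669 times the autosomal one. Promoter peaks were present at 34.5% ± 0.796 of X genes and 54.2% ± 1.08 of autosomal genes (SD, n = 3). Both differences were larger than the spread between libraries and in the same direction in each. The ratio depended on the peaks used and was 0.281 with the taller 50% of peaks. The cells are labelled female, and the promoters of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had no peak in any library, whereas those of their X-linked partners Ddx3x, Eif2s3x, Kdm5c and Kdm6a had one in every library. Peaks on the Y chromosome numbered 36, 43 and 22 in replicates 1, 2 and 4, in 51 merged regions. The reference sequence of 43 of these regions (84.3%) matched another chromosome at 90% identity or more over at least 50% of its length, against 48% of 150 random Y windows. The 8 other regions lay together near the end of the chromosome, between 90738398 and 90744080. Of these, 4 held a peak in all 3 libraries, and the longest single match covered 0% to 19.9% of their sequence. Shorter matches were not added up, so more of the sequence may have a match. The origin of these peaks in cells labelled female was not tested.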

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

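The minimum height of 0.4, and the coding TSS in place of the 5' end of the gene record as the centre of the distal window, were chosen after the results were seen, as was the use of single libraries for the subset tests. The 5' end of the gene record gave the same 10 distal calls. No called result changed its direction. The monocyte list was above all 14 lists in every setting but the taller 50% of peaks, where its distal mean was above 13 and below that of neutrophil granule genes (difference -0.0667, permutation test, adjusted p = 0.970). Across settings, 9 of 11 alternatives kept the number of distal calls within 1.5 times of 10 (from 9 to 13, with leave-one-out counts of 9 to 11), and 7 of 9 kept the promoter calls within 1.5 times of 7 (6 to 9 when a library was left out). The motif count of 10 stayed between 9 and 12, and the footprint count between 113776 and 131812 when a library was left out. In the comparisons of single lists, 13 promoter and 14 distal calls were lost and 5 and 4 gained over all settings. Leaving out each library gave 45818 to 51513 peaks per library, 33.8% to 36.1% of peaks near a TSS, an X ratio of 0.361 to 0.368 and 10 to 11 motifs.

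With the authors' shorter list, 42.4% of peaks lay near a TSS, the X to autosome density ratio was 0.327 and 2 lists passed the promoter test. With the taller 50% of peaks there were 24280 peaks per library, 70.2% of regions were shared, 48.4% of peaks lay near a TSS, the X ratio was 0.281, and 0 promoter calls (4 at an unadjusted p under 0.05 by Fisher's exact test) and 3 distal calls stood. Fewer peaks enter by construction in both settings. The share near a TSS was 28.6% with a 500 bp window and 41.4% with 2.5 kb, a change set by the window's width. With 100 kb around the gene 6 distal calls stood; the cause was not tested. The X ratio was 0.316 with equal peak numbers and 0.313 with a minimum height of 0.4, which removed low peaks; the cause was not tested. Sharing among the libraries left was 63.3% to 67.5% without 1 library, where fewer libraries have to share a region.

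The planned stricter footprint setting was not run because the deposited footprint value is constant. No paired analysis was possible because there is 1 group. The height scale is unknown, so depth limits cannot be put on single peaks. Of 193 named genes the mean number of distal peaks moved over 1.5 times for 134 with the taller 50% of peaks, 82 with the shorter list, 11 with equal peak numbers and 7 without peaks under 0.4.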

Other observations

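Of the tests here, those on crowded windows, on gene density, on the monocyte subsets and on the CpG content of single lists were chosen only after the result was seen. Genes of the nonclassical (patrolling) and classical monocyte subsets had unequal shares of open promoters, by a margin that depended on the library. Of 13 nonclassical genes 10 had a promoter peak in all 3 libraries, among them Nr4a1, Cx3cr1 and Pou2f2, an octamer-binding factor gene, while Ace and Cd36 lacked one in some libraries and Cd300e in all. Of 12 classical genes 4 did (Sirpa, Gda, Mmp8 and Fn1), and Ccr2, the receptor for the chemokine that draws classical monocytes to inflamed tissue, Plac8 and Chil3 had no promoter peak in any library. The difference of 43.6 percentage points gave p = 0.0472 in 1 unplanned Fisher's exact test. It lay above the 95% range of pairs of random lists with the same promoter CpG content, -17.9 to 37.8 points. Without replicate 4 the counts were 10 and 5, a difference of 35.3 points inside that range (exact test, p = 0.111). It was 43.6 points without replicate 1 and 42.9 without replicate 2. In single libraries it was 17.9, 26.9 and 50.6 points in replicates 1, 2 and 4, outside the matched range only in replicate 4, so the difference is not settled by these data. Distal peaks, 6.74 ± 1.75 per nonclassical and 4.44 ± 0.625 per classical gene (SD, n = 3), did not differ (permutation test, p = 0.143). Plac8 had 9 ± 2 distal peaks and Sirpa, a receptor that restrains phagocytosis, 11.3 ± 2.08 (SD, n = 3).

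Promoter CpG content moved the lists apart from their raw counts. Against random lists of equal CpG content, 68.4% of Fc and complement receptor promoters were open in all libraries where those lists averaged 21.9%. The values were 72.7% against 18.5% for class II promoters, and 60% against 21.8% for cytokine promoters. Pattern recognition genes stood at 65% against 31.5%, interferon response genes at 58.8% against 26.9%, and myeloid transcription factor genes at 90% against 63.0%. Neuronal genes, whose promoters are rich in CpG, stood below their CpG-matched lists at 21.4% against 51.8%, as did epithelial genes at 14.3% against 41.6% and T cell genes at 6.67% against 28.2%. Lists without an immune role also stood above theirs, lysosomal genes at 100% against 58.2% and housekeeping genes at 100% against 74.5%, as did dendritic cell genes at 57.1% against 33.9%. B cell, natural killer cell, erythroid, mast cell and basophil, and hepatocyte genes lay within their matched ranges. Chemokine receptor genes, at 26.3% against 20.4%, lay within the matched range of 5.26% to 36.8%.

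The lead of the monocyte list over the other lineages was weighed against CpG content and gene density. Among 198 genes of the other lineages 19.7% had a promoter peak in all libraries, against 60% of monocyte genes. The difference of 40.3 points stood at percentile 100 of 10000 pairs of random lists matched on CpG content, whose central 95% ran from -20.5 to 13.7 points. The difference of 3.57 distal peaks stood at percentile 100 of pairs matched on the number of TSSs around the genes (-1.39 to 1.47). Both explanations are therefore argued against as the whole cause, with CpG content taken at the most upstream coding TSS. High matched ranks were not particular to monocyte genes. Housekeeping, lysosomal and dendritic cell genes stood at percentiles 99.7, 100 and 99.1 for promoters and 99.6, 100 and 99.2 for distal peaks. Hepatocyte genes stood at 4.1 and 16.5. Monocyte-specific regulation is a hypothesis that may explain the rest, not told apart from features shared with other lists. It was untested here without another cell type.

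Some windows of 50 kb were crowded with peaks in 1 library. In 16 windows 1 library held at least 10 peaks and at least 3 times as many as either other, 4 in replicate 1, 12 in replicate 2 and 0 in replicate 4, over genes such as Itgam, Itgax, H2-Ob and Zbp1. In 14 windows the median height of these peaks was under the 5th percentile of that library's peaks elsewhere, and in 0 windows was it at or above the 25th percentile, which argues against new open sites of ordinary height. Where windows held regions shared by all libraries, these had a median relative height of 1.05 (quartiles 0.970 to 1.09, 23 regions), which argues against a doubled copy number there. Other windows held no shared region, so copy number could not be tested in them. Among these was the window with the most peaks, 51 in replicate 2, at 3000001 to 3050000 on chromosome 17. A lower calling threshold in those windows is a candidate explanation that stays open, and no further biological explanation was tested.

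Promoter peaks of the X chromosome were lower as well as rarer. Over 303 X and 10708 autosomal genes with a promoter peak in all libraries, the ratio of median heights was 0.549 ± 0.0192, and 0.636 ± 0.0285 against autosomal genes of equal CpG content (SD, n = 3), with a largest upper end of 0.751 over the libraries. CpG content at the most upstream TSS, as the whole cause, is argued against by that bound. The ratio allows accessibility of 1 of the 2 X copies in each female cell. For distal peaks the ratio of median heights, not matched on CpG content, was 0.705 ± 0.0451 (SD, n = 3). Genes that are known to escape X inactivation stood above the autosomal median, at 1.62 ± 0.225 times for Kdm5c, 2.76 ± 0.0670 for Kdm6a, 1.43 ± 0.0689 for Ddx3x and 1.30 ± 0.0789 for Eif2s3x (SD, n = 3). That median was not matched on CpG content, and no comparable inactivated X genes were set beside these genes. Their heights therefore do not test the explanation. Lower activity of X genes in general stays open, since no male cells were analysed here.

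The tallest region of the libraries, at 39846781 to 39846900 on chromosome 17, outside protein-coding genes, had heights of 113, 88.8 and 115 in replicates 1, 2 and 4. Among the next were regions in Cers5 on chromosome 15 (53.1, 55.4 and 49.9), in Lars2 on chromosome 9 (54.2, 45.6 and 58.3) and in Mid1 on the X chromosome (26.9, 25.3 and 33.8). The Mid1 region lies beside Gm21887, the gene with the most distal peaks. Replicate 4 had the largest step of heights, more peaks than replicate 2 and the tallest shared regions, at 1.42 times the deposited height in replicate 2 (median).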
